A study of Mus musculus with 2 samples.

How the data were processed

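H3K9ac ChIP-seq peak lists from the intestine of B6NCrl mouse embryos at day 15.5 were analysed for 1 group of 2 biological replicates, made of 78 (replicate 1) and 62 (replicate 2) pooled embryos of both sexes per the labels. There were 4 peak lists: 1 for each replicate, 1 called on both replicates together (pooled) and 1 of replicated peaks, derived by the authors from the pooled list and the replicate lists per the text files deposited beside them. The rule by which a pooled peak was kept as replicated, the aligner, the peak caller, its filters and its thresholds are not given in the sources used here. The genome build is mm10, per the labels. Each list has the narrowPeak format. Column 7 holds the authors' fold enrichment of the peak, taken as a linear ratio over background as deposited, and columns 8 and 9 hold the −log10 of its p-value and q-value as the authors' caller gave them. These values belong to the peak within its own list, and they were used to describe, rank or filter peaks. Of columns with per-sample values, 0 were left unmatched to a sample.

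No read or fragment counts were used here, so the depth of each replicate and the precision of a single fold value are unknown, and a longer list may come from a deeper library. The smallest −log10 p was 2.11 in replicate 1 and 2.01 in replicate 2, and 70.5% and 65.8% of their peaks had a −log10 q of 2 or more. The replicates are separate pools of embryos, but with n = 2 an SD has little precision. Tests across genes treat genes as units, which are not replicates, so their p-values describe these libraries.

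Peaks on chromosomes 1 to 19 and X were used. Left out were 11 peaks of replicate 1, 10 of replicate 2, 13 pooled and 7 replicated ones. Gene models were those of GENCODE M21 on GRCm38, the assembly that mm10 names, and 0 peaks ran past the end of a chromosome. Gene symbols are those of the annotation, and where a symbol was repeated 1 gene was kept, which left 21728 protein-coding genes. Coordinates are 1-based. Peaks were counted as shared when they overlapped by at least 50% of either peak's length (bedtools 2.31.1). Chance overlap came from 100 shuffles of the peaks within their chromosomes, outside assembly gaps. A peak lay at a TSS when it overlapped the 1 kb either side of an annotated TSS of any gene type, among 130588 distinct positions, and otherwise in another exon, an intron or intergenic sequence, in that order. A protein-coding gene had a TSS peak when a replicated peak overlapped the 1 kb either side of any of its protein-coding TSSs. Its fold was the highest of such peaks, given as the mean ± SD of the replicates' own lists. Promoters were CpG-rich at an observed to expected CpG ratio of 0.6 or more and a GC content of 0.5 or more in the 500 bp either side of the 5' end. Domains joined replicated peaks less than 1 kb apart. Distal peaks lay more than 2.5 kb from any TSS, and were counted for a gene between 2.5 and 100 kb from its 5' end.

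The 29 gene lists were fixed before the data were examined: 12 of cell types of the intestine, 12 of other tissues and 5 of general or positional functions. They were intestinal epithelium, stem and progenitor cells, enterocyte brush border, goblet and Paneth cells, enteroendocrine cells, smooth muscle, gut mesenchyme, enteric neurons and glia, interstitial cells of Cajal, mesothelium, endothelium, and blood and immune cells. The other tissues were hepatocytes, pancreas, stomach and lung, skeletal muscle, heart, central nervous system, keratinocytes, kidney, germ cells, photoreceptors, pluripotency, and olfactory and vomeronasal receptors. The last were cytosolic ribosomal proteins, proteasome, cell cycle, Hox groups 1 to 9 and Hox groups 10 to 13. All listed genes matched an annotated symbol. Shares with a TSS peak were compared with all other protein-coding genes by Fisher's exact test, domain widths by a permutation test of the median among genes with a TSS peak (lists with 5 or more), and distal peaks by a permutation test of the mean. Tests were two-sided, permutations had 100000 resamples, and p-values were adjusted by the Benjamini-Hochberg method over the lists of each family, at a threshold of 0.05. Shares have 95% Wilson intervals, which cover counting error only. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

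The genes named were set by rule. For each intestinal list they were the 4 members with the highest mean fold at the TSS and up to 4 without a replicated TSS peak in alphabetical order, and for each other list 2 and 2. Over all genes they were the 10 with the widest domain and the 10 with the highest fold, with the 5 distal peaks of highest fold and 24 genes fixed by name. In the closing section, other genes are named that were chosen after their values were seen.

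The tests were tested on simulated data. Among 40 random lists of 25 genes, with 95% of members given a peak over the real states of 21728 genes, Fisher's exact test called 37, and it called 0 of 200 lists left as they were. With widths multiplied by 2 over 13759 genes, 40 of 40 lists were called and 2 of 200 unchanged ones. With 2 distal peaks added to each member over 21728 genes, 40 of 40 were called and 1 of 200 unchanged ones. Random lists of CpG-rich genes alone were called in 200 of 200 cases by Fisher's exact test at an unadjusted p under 0.05, and in 2 of 200 by the exact test within CpG classes. After 60.0% of the 51154 peaks of replicate 1 were kept, the overlap with the full list was found to be 60.0%. The kept peaks had unchanged coordinates, so this checks the counting alone and not the overlap rule on shifted peaks.

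Alternatives covered the overlap that counts as shared (1 bp, or 50% of both peaks), peaks with a −log10 q of 2 or more or a fold of 4 or more, lists of equal length, TSS windows of 500 bp and 2.5 kb, and the gene's 5' end alone. Others were a test within CpG-rich and CpG-poor promoters, a stricter CpG definition (0.75 and 0.55), joining distances of 0 and 3 kb, distal limits of 50 and 200 kb, matching on gene density in 5 bins, and each replicate's own list in place of the replicated one. After the data were seen, 3 alternatives were added: each peak counted for the nearest gene only, domains at 1 protein-coding gene only, and matching on fold in 10 bins. Where replicate 1 is left out the values come from replicate 2's own list, and the reverse.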

Results

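Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map H3K9ac, the acetylated form of lysine 9 of histone H3, in the intestine of mouse embryos. The mark lies mainly at the promoters of genes in use. Tissue came from B6NCrl embryos of both sexes at embryonic day 15.5, a stage at which the gut tube holds a folding epithelium, a layered mesenchyme with smooth muscle, and an enteric nervous system. The samples form 1 group of 2 biological replicates, the first from 78 pooled embryos and the second from 62. There was no other stage, tissue or treatment, so the comparisons were between the replicates and between groups of genes within the tissue. Read totals are not known from the peak lists, so the depth behind each peak is unknown.

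Protein-coding genes with a peak in both replicates were ranked by the mean fold of their H3K9ac sites. Genes that lacked a peak in either replicate had no mean and could not be ranked. The 10 protein-coding genes with the highest fold enrichment at a transcription start site (TSS) were Wtap, H3f3a, Srsf6, Kmt5b, Irf2bp2, Rpsa, Arid1a, Actg1, Ddx6 and Srsf4. Wtap encodes a subunit of the RNA methylation complex, H3f3a a histone H3.3, Srsf6 and Srsf4 splicing factors, Rpsa a protein of the small ribosomal subunit and Actg1 cytoplasmic actin. The peak at Wtap had a mean fold of 29.7 ± 1.06 (SD, n = 2) and lay at chromosome 17, positions 12990713 to 12993314 of mm10, over the 5' UTR and an intron. The peak at Srsf4 had a mean fold of 25.02 ± 0.488 (SD, n = 2).

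Weak sites were shared far less often than strong ones. Replicate 1 had 51154 peaks on chromosomes 1 to 19 and X and replicate 2 had 57075. Of these, 53.8% of the peaks of replicate 1 (95% Wilson interval 53.3 to 54.2) overlapped a peak of replicate 2, and 46.8% of those of replicate 2 (46.4 to 47.2) overlapped one of replicate 1. Peaks shuffled within chromosomes overlapped in 1.84% ± 0.0619 and 1.64% ± 0.0536 of cases (SD over 100 shuffles). Among peaks with a fold of 10 or more, 100% of those of replicate 1 and 99.96% of those of replicate 2 were shared, and below a fold of 3 the shares were 20.3% and 13.2%. The intervals cover counting error over peaks alone, and the share moved with the overlap required and with the peak threshold.

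**Figure D1:**
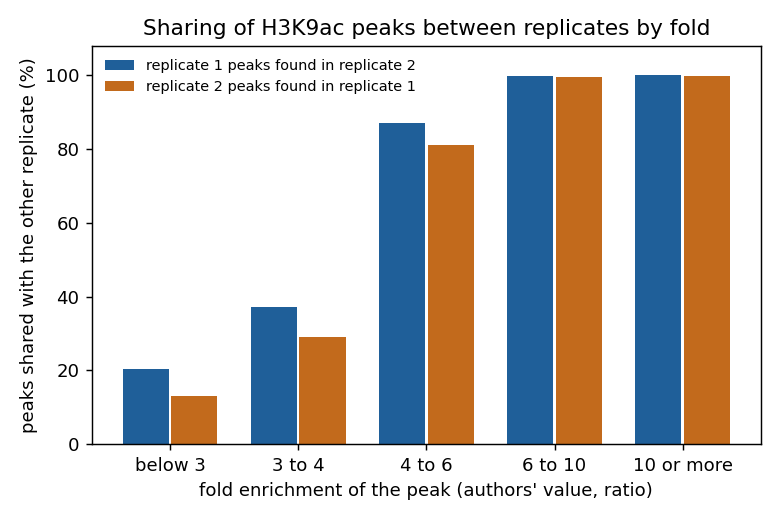
Percentage of each replicate's H3K9ac peaks that overlap a peak of the other replicate (vertical axis), in bins of the authors' fold enrichment (horizontal axis, a ratio), with 1 bar per replicate. Sharing is 20.3% and 13.2% below a fold of 3 and 100% and 99.96% at a fold of 10 or more.

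Promoter peaks made up most of what the replicates shared, and peaks away from promoters most of what they did not. Of the shared peaks, 78.6% lay within 1 kb of a TSS in each replicate, at a median fold of 5.49 in replicate 1 and 6.11 in replicate 2. Of the peaks in replicate 1 alone, 24.5% lay at a TSS, at a median fold of 2.88, and of those in replicate 2 alone 23.6%, at 2.92. Across 24640 sites found in both lists, the authors' fold values had a Spearman rho of 0.878, which fell to 0.530 over the 3914 sites more than 2.5 kb from a TSS. The SD of the log2 ratio of the replicates' folds was 0.423 over all these sites and 0.404 over the distant ones. The lower rho thus did not come with a wider spread between the replicates. Sites are not independent replicates, so no p is given.

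The list that the authors call replicated held 28084 peaks on these chromosomes, or 44.4% of the 63182 peaks called on both replicates together. Its peaks had a median width of 771 bp and a median fold of 5.58, against 227 bp and 2.48 for the pooled peaks left out of it. At a TSS lay 72.3% of replicated peaks and 23.5% of the pooled peaks left out. Replicated did not always mean found in both replicates' own lists. Of the 28084 peaks, 24640 overlapped a peak of each replicate by the overlap counted as shared. With an overlap of 1 bp, 24926 of all pooled peaks did. Of the 5414 replicated peaks more than 2.5 kb from a TSS, 3914 met the rule for shared peaks in both replicates.

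In the embryonic intestine, replicated H3K9ac peaks were concentrated at gene starts. Of the 28084 peaks, 72.3% overlapped the 1 kb either side of an annotated TSS, against 9.10% ± 0.168 of shuffled peaks (SD over 100 shuffles). Introns away from any TSS held 13.01% of peaks against 34.6% of shuffled ones, other exons 5.05% against 7.83%, and intergenic sequence 9.69% against 48.4%. In the replicates' own lists the share at a TSS was 53.6% and 49.3%.

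A gene was counted as marked where a replicated peak overlapped the 1 kb either side of any of its TSSs. Such a TSS peak was found at 13759 of 21728 protein-coding genes, or 63.3% (95% Wilson interval 62.7 to 64.0), and at 65.1% ± 0.651 in the replicates' own lists (SD, n = 2). Both replicate lists had a TSS peak at 13659 genes, replicate 1 alone at 388 and replicate 2 alone at 588. Of the genes with a TSS peak in a single replicate's list, 178 were counted as marked in the replicated list. Promoters rich in CpG dinucleotides, typical of housekeeping and developmental genes, carried the mark in 95.8% of 9722 genes. CpG-poor promoters, typical of genes restricted to mature cell types, carried it in 37.0% of 12006 genes, an odds ratio of 39.1 by Fisher's exact test, two-sided. The class was taken at the gene's 5' end, but the peak could lie at any of its TSSs. Class and peak may therefore belong to different promoters of a gene, here and in the tests within CpG classes. The median fold at marked genes was 12.01 for CpG-rich and 7.39 for CpG-poor promoters.

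Regulators and structural genes of the intestinal epithelium were marked nearly throughout. Of 36 genes in the list fixed for it, 35 had a TSS peak (97.2% against 63.3% of other genes, adjusted p = 1.23e-05 by Fisher's exact test), the exception being Fabp1, a fatty acid binding protein of enterocytes. The highest mean folds in the list were at Foxa3, at 14.4 ± 0.384, Gata5, at 11.3 ± 0.249, Grhl2, at 11.1 ± 0.388, and Gata6, at 11.0 ± 0.792 (SD, n = 2), which encode transcription factors of endoderm or epithelium. The Foxa3 peak lay outside the gene, its middle 1302 bp from the 5' end, in a domain at 2 protein-coding genes. Its fold may therefore not belong to Foxa3 alone. Cdx2, the homeobox factor that specifies intestinal identity, had a mean fold of 11.0 ± 3.35 (SD, n = 2). Its strongest peak spanned chromosome 5, positions 147300973 to 147307195, over the 5' UTR, coding exons, introns and 3' UTR. Cdx1 stood at 8.68 ± 0.944, the hedgehog ligands Ihh at 10.8 ± 0.841 and Shh at 6.96 ± 1.37, the nuclear receptor gene Hnf4a at 5.89 ± 1.31, and Vil1, which encodes the actin-bundling protein villin, at 5.01 ± 1.55 (SD, n = 2). The Hnf4a peak, at chromosome 2, positions 163547124 to 163547980, covered an internal promoter whose middle lay 40744 bp from the gene's 5' end.

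Genes of intestinal stem and progenitor cells were also marked, with 17 of 18 carrying a TSS peak (94.4%, adjusted p = 0.00783 by Fisher's exact test). The exception was Olfm4, a marker of adult crypt stem cells. The strongest were Lgr4, a receptor for R-spondins, at a mean fold of 20.0 ± 1.80, Lrig1 at 18.1 ± 3.32, Ephb3 at 15.5 ± 2.27 and Bmi1 at 15.4 ± 0.313 (SD, n = 2). Lgr5, the receptor that marks crypt base columnar cells in the adult, had a weaker peak of 3.99 ± 0.611 (SD, n = 2) over the 5' UTR, a coding exon and an intron at chromosome 10, positions 115586799 to 115587985. Within CpG-rich and CpG-poor promoters taken separately the list no longer passed, with an adjusted p of 0.0760.

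Genes of mature absorptive and secretory cells were marked less often than other genes. For the enterocyte brush border 9 of 25 genes had a TSS peak (adjusted p = 0.00868), for goblet and Paneth cells 4 of 16 (adjusted p = 0.00497) and for enteroendocrine cells 7 of 22 (31.8%, adjusted p = 0.00555), by Fisher's exact test. Lct and Sis, which encode the disaccharidases lactase and sucrase-isomaltase, had no replicated TSS peak, nor did Muc2, the main intestinal mucin, or Neurog3, the factor that commits cells to the endocrine lineage. Also without one were Abcg5, Alpi, Aqp8 and Car4 of the brush border, Agr2, Ang4, Clca1 and Fcgbp of goblet and Paneth cells, and Arx, Chga, Chgb and Gcg of endocrine cells. Among the marked members, Mttp, which loads lipid onto apolipoprotein B, stood at 12.4 ± 0.177, Dpp4 at 8.197 ± 3.60, Anpep at 8.11 ± 0.0625 and Apob at 6.24 ± 1.69 (SD, n = 2). The Mttp peak lay in a domain at 2 protein-coding genes, so its fold may not belong to Mttp alone. Atoh1, the factor of the secretory lineage, had a weak peak of 3.67 ± 0.444, beside Creb3l1 at 10.2 ± 1.19, Gfi1 at 4.00 ± 0.342 and Creb3l4 at 3.55 ± 0.330 (SD, n = 2). The endocrine genes Sct, Isl1, Rfx6 and Insm1 stood between 4.03 and 6.52. By the exact test within CpG classes the brush border list no longer differed from other genes (adjusted p = 0.864) and the goblet and Paneth list no longer passed (0.0678). By Fisher's exact test, replicate 2's own list had 7 of the 16 goblet and Paneth genes (43.8%, adjusted p = 0.139) and replicate 1's had 6 (37.5%, 0.0513), and replicate 1's own list had 11 of the 25 brush border genes (44.0%, 0.0530).

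The mesenchyme of the gut was marked throughout: all 33 genes in its list had a TSS peak in the replicated list and in each replicate's own (adjusted p = 3.32e-06 by Fisher's exact test). The highest mean folds were at Ptch1, the hedgehog receptor, at 20.3 ± 2.52, Meis1 at 15.6 ± 3.40, Hlx at 14.7 ± 3.24 and Meis2 at 13.9 ± 0.381 (SD, n = 2). Foxf1, a mesenchymal target of hedgehog signalling, stood at 11.9 ± 2.69, with its strongest peak over the whole gene from the 5' UTR to the 3' UTR at chromosome 8, positions 121084343 to 121087884. Gli1, another such target, stood at 5.70 ± 0.549 (SD, n = 2).

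Smooth muscle genes carried a TSS peak in 17 of 18 cases (94.4%, adjusted p = 0.00783 by Fisher's exact test), the exception being Kcnmb1, a potassium channel subunit. Srf, whose product switches on contractile genes, had the highest mean fold at 21.7 ± 1.80, followed by Tpm1 at 14.8 ± 0.624, Smtn at 7.89 ± 1.92 and Flna at 7.83 ± 0.567 (SD, n = 2). Myocd, the cofactor of Srf, stood at 5.14 ± 1.65 (SD, n = 2). The peak of Myh11, the smooth muscle myosin heavy chain, lay just upstream of the gene at chromosome 16, positions 14292306 to 14292856, with a fold of 4.05 in the replicated list and no TSS peak in replicate 1's own list. The list was not past the threshold in replicate 1's own list, where 16 of the 18 genes were marked (adjusted p = 0.0597 by Fisher's exact test), or with only peaks of fold 4 or more (83.3%, 0.0581).

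Genes of the minor cell types of the gut wall were marked at shares that did not pass the test. A TSS peak was found at 14 of 26 genes of enteric neurons and glia (53.8%, adjusted p = 0.353), all 5 of interstitial cells of Cajal, the pacemaker cells of the gut (adjusted p = 0.192), 5 of 8 of mesothelium (62.5%, adjusted p = 1.00) and 15 of 22 of endothelium (68.2%, adjusted p = 0.855), by Fisher's exact test. The Cajal cell list was at its highest possible share, with an unadjusted p of 0.166 by Fisher's exact test. With 5 genes it was thus too short to pass as higher by that test. Within CpG classes it passed as higher (adjusted p = 0.0445 by the exact test). With only peaks of fold 4 or more the enteric list passed as lower (30.8%, adjusted p = 0.00575 by Fisher's exact test). Hand2, Erbb3, Ednrb and Elavl4 led the enteric list with mean folds between 7.04 and 12.5, Ret, the receptor of enteric progenitors, stood at 5.69 ± 0.973 and Sox10 at 3.42 ± 0.426 (SD, n = 2). Phox2b, a factor needed for enteric neurons, had no TSS peak in the replicated list or in either replicate's own, and Chat, Fabp7, Foxd3 and Gfap had one in a single replicate's list only. Kit stood at 7.31 ± 4.13, Etv1 at 7.20 ± 0.343, Ano1 at 6.27 ± 1.31 and Cd34 at 5.12 ± 0.540 (SD, n = 2). Of mesothelial genes Bnc1, Rspo1 and Wt1 stood between 3.58 and 4.74, while Gpm6a, Msln and Upk1b were unmarked. Endothelial Fli1, Ets1, Egfl7 and Prox1 stood between 7.41 and 13.6, and Cdh5, Emcn, Flt4 and Lyve1 had no replicated TSS peak.

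Blood and immune genes were marked less often than other genes, in 5 of 24 cases (20.8%, adjusted p = 0.000127 by Fisher's exact test), which was not past the threshold within CpG classes (adjusted p = 0.173). The marked members with the highest mean fold were Klf1, at 12.4 ± 0.727, Runx1, at 8.24 ± 0.184, Gypa, at 4.60 ± 1.35, and Ikzf1, at 4.43 ± 0.156 (SD, n = 2). The macrophage genes Adgre1, C1qa, C1qb and C1qc had no TSS peak.

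Most lists of genes that define other organs were marked less often than other genes. The shares were 1 of 18 for hepatocytes (adjusted p = 3.32e-06), 1 of 14 for stomach and lung (7.23e-05), 4 of 14 for pancreas (0.0138), 3 of 15 for skeletal muscle (0.00174), 2 of 13 for heart (0.00134), 2 of 12 for keratinocytes (0.00250) and 3 of 12 for kidney (0.0153), all lower than among other genes by Fisher's exact test. They were 1 of 16 for germ cells (1.47e-05), 0 of 10 for photoreceptors (0.000127), 1 of 8 for pluripotency (0.00780) and 2 of 1418 for olfactory and vomeronasal receptors. The own lists of replicate 1 and replicate 2 marked 2 and 1 genes for hepatocytes, 2 and 3 for stomach and lung, 5 and 6 for pancreas, 4 and 5 for skeletal muscle, 3 and 4 for heart and 4 and 6 for kidney. They marked 3 and 2 for germ cells, 1 and 2 for photoreceptors and 5 and 8 for olfactory and vomeronasal receptors. The central nervous system list had 8 of 19 (42.1%, adjusted p = 0.0730 by Fisher's exact test), which passed as lower within CpG classes (0.00200) and with only peaks of fold 4 or more (15.8%, 0.000364). Alb, the liver's albumin, had no TSS peak in the replicated list or in either replicate's own, and Sox2, a factor of the foregut, and Myod1, of skeletal muscle, had one only in replicate 1's own list, at folds of 3.48 and 2.64. Pdx1, a factor of pancreas and duodenum, had a weak peak of 3.49 ± 0.487 (SD, n = 2) over its 5' UTR, a coding exon and an intron at chromosome 5, positions 147270177 to 147270926. The calls for pancreas (adjusted p = 0.161), keratinocytes (0.268), kidney (0.0623) and pluripotency (0.303) were not past the threshold by the exact test within CpG classes, and those for pancreas and kidney were past it in neither replicate's own list. Replicate 1's own list marked 3 of the 8 pluripotency genes (adjusted p = 0.170 by Fisher's exact test).

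Some of the marked members of these lists shared a peak with a neighbour or with an internal promoter. The peaks at Mylpf (mean fold 16.8), a skeletal muscle light chain, at Nphs1 (2.91), of the kidney glomerulus, and at Vmn1r4 (10.4), a vomeronasal receptor, lay nearer to the TSS of another protein-coding gene. Those at Krt10, Esrrb and Olfr94 lay at an internal TSS and not at the gene's 5' end, as did those at Anpep, Ano1, Ets1, Egfl7, Runx1 and Sox10. The other leading members were Mafa and Nkx6-1 of pancreas, Foxj1 of stomach and lung, Ryr1 of skeletal muscle, Ryr2 and Myl7 of heart, Mbp and Slc17a7 of the nervous system, Krt10 and Dsc3 of keratinocytes, Lhx1 of kidney, Dazl of germ cells, Esrrb of pluripotency and Olfr94, with mean folds between 3.17 and 9.13. Members without a replicated TSS peak, in alphabetical order by list, were Afp and Ahsg, Cel and Cpa1, Atp4a and Atp4b, Acta1 and Ckm, and Actc1 and Myh6. The others named were Emx1 and Emx2, Dsg3 and Flg, Aqp2 and Cdh16, Acr and Ddx4, Arr3 and Crx, Dppa3 and Dppa4, and Olfr1 and Olfr10. Of these, Cel, Ckm, Myh6, Emx1 and Emx2 had a TSS peak in replicate 2's own list only, and Cdh16 and Dppa3 in replicate 1's only. With the gene's 5' end alone, Ckm counted as marked.

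Genes of general cell functions were marked nearly throughout. TSS peaks were found at 80 of 83 cytosolic ribosomal protein genes (adjusted p = 1.37e-11), 37 of 39 proteasome genes (2.79e-05) and all 20 cell cycle genes (0.000533), by Fisher's exact test. Rpsa at 26.4 ± 0.591 and Rps19 at 24.4 ± 1.17 led the ribosomal list, Psmd1 at 20.0 ± 1.199 and Psmd6 at 19.6 ± 1.24 the proteasome list, and Aurka at 15.2 ± 2.097 and Mcm4 at 13.6 ± 2.66 the cell cycle list (SD, n = 2). The peaks of Aurka and Mcm4 lay outside the gene, each in a domain at 2 protein-coding genes. Among the unmarked ribosomal protein genes were Rpl10l and Rpl39l, and the unmarked proteasome genes were Psma8 and Psmb11. Within CpG classes the cell cycle list had an adjusted p of 0.0591.

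Hox genes, which encode position along the body, were marked over most of the 4 clusters. Of the genes of groups 1 to 9, 25 of 27 had a TSS peak (92.6%, adjusted p = 0.00202 by Fisher's exact test), with Hoxb1 and Hoxc9 marked only in replicate 2's own list. Hoxa4 at 12.3 ± 0.0875 and Hoxb4 at 12.3 ± 1.05 had the highest mean folds (SD, n = 2). Of groups 10 to 13, which pattern the hind end of the body, 6 of 12 were marked (adjusted p = 0.404 by Fisher's exact test). They were led by Hoxa10 at 5.02 ± 0.413 and Hoxa11 at 4.72 ± 0.566 (SD, n = 2). Hoxb13 had a TSS peak only in replicate 2's own list, and Hoxc11 had none in either replicate's. With only peaks of fold 4 or more, groups 10 to 13 passed as lower, at 3 of 12 (adjusted p = 0.0405 by Fisher's exact test). The difference between these lists was not tested.

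**Figure D2:**
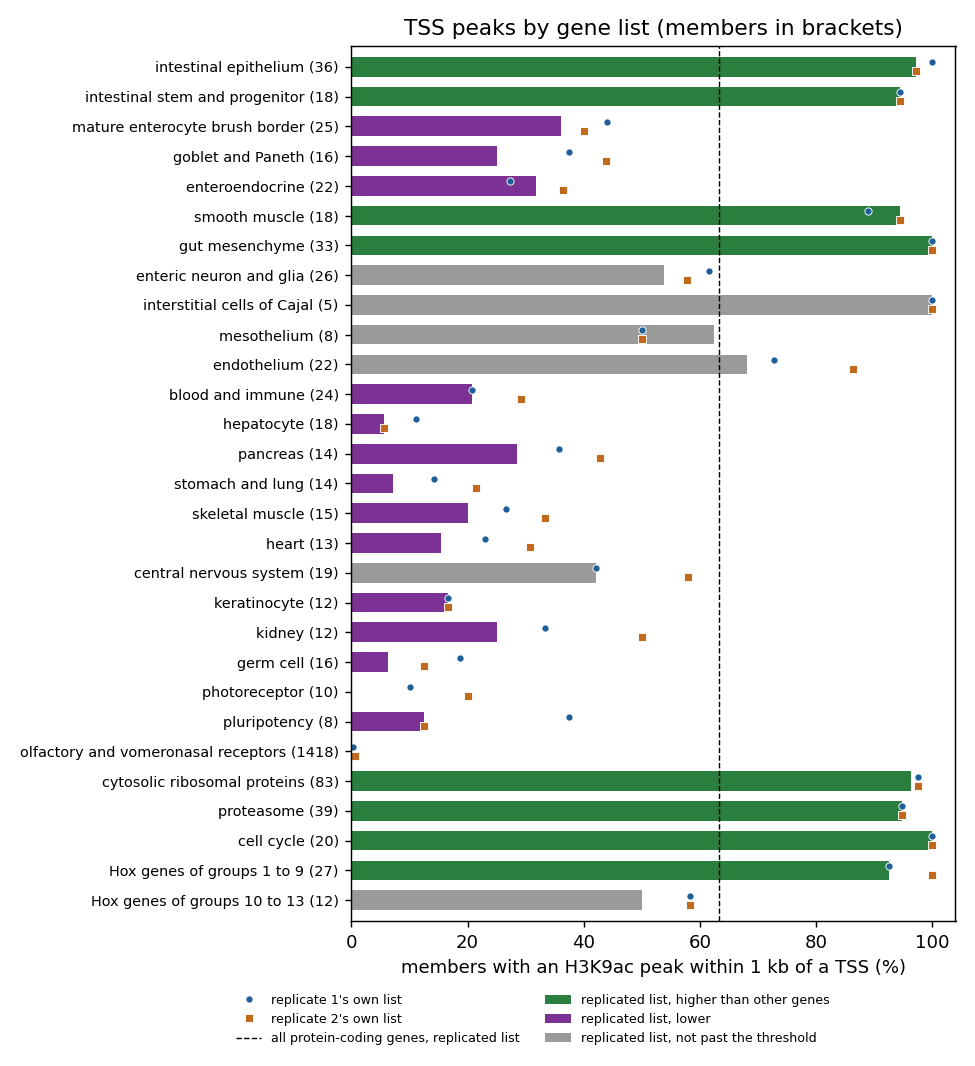
Percentage of the members of each of 29 gene lists with an H3K9ac peak within 1 kb of a TSS (horizontal axis), in the replicated list (bars) and in each replicate's own list (circles, replicate 1, and squares, replicate 2), with the 63.3% of all protein-coding genes as a dashed line. Gut mesenchyme reaches 100% and intestinal epithelium 97.2%, and photoreceptor genes stand at 0% in the replicated list.

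The widest H3K9ac domains included those over Hox genes, Meis1, Meis2 and Ptch1. Domains were made by joining replicated peaks less than 1 kb apart. The widest at a protein-coding TSS, of 29226 bp, lay at chromosome 11, positions 96299075 to 96328300. It covered Hoxb4 and Hoxb5 in full, with the end of Hoxb6 and the start of Hoxb3. Those that followed lay at Bahcc1 (16813 bp), Meis2 (16735 bp), Hoxa1 with Hoxa2 (15852 bp), Meis1 (14616 bp) and Ptch1 (14456 bp). Foxf1, with 13691 bp, ranked 11 among all genes, Cdx2, with 10300 bp, ranked 31 and Shh, with 10114 bp, ranked 33.

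By list, genes with a TSS peak had wider domains than other marked genes in gut mesenchyme (median 3435 bp against 1698 bp), intestinal epithelium (3388 bp), Hox groups 1 to 9 (3083 bp) and ribosomal proteins (2493 bp), each with an adjusted p of 8.5e-05 in a permutation test of the median, which rests on the smallest p that 100000 resamples can give, 2e-05. Neighbouring Hox genes share a domain and are not separate units. With domains at 1 protein-coding gene alone, groups 1 to 9 had a median of 2380 bp (adjusted p = 0.0123, permutation test). Wider domains were also found for stem and progenitor genes (2774 bp, adjusted p = 0.00459), cell cycle genes (2523 bp, 0.0122) and smooth muscle genes (2490 bp, 0.0315), by the same permutation test. Enteroendocrine genes had narrower ones (553 bp, 0.00190, over 7 genes), with medians of 666 bp in replicate 1's own list and 362.5 bp in replicate 2's. In the remaining 9 of the 17 lists with 5 or more marked genes the difference did not pass, among them enteric neurons and glia (1245 bp, 0.160), brush border (1286 bp, 0.345), endothelium (1532 bp, 0.641) and proteasome (1510 bp, 0.412). Others were Cajal cells (2142 bp, 0.502), mesothelium (956 bp, 0.160), blood (1480 bp, 0.690), the nervous system (1135 bp, 0.160) and Hox groups 10 to 13 (1550 bp, 0.708). With single peaks in place of domains the smooth muscle median was 1045 bp, below that of other genes (adjusted p = 0.203, permutation test), and the cell cycle call was lost (0.421). In replicate 1's own list the smooth muscle call was lost too (2246 bp, adjusted p = 0.0653, permutation test), and among genes of like fold, a comparison added after the data were seen, so was the enteroendocrine one (0.344). Nervous system genes passed as narrower in replicate 1's own list (311 bp, adjusted p = 9.5e-05), in replicate 2's (372 bp, 0.000252) and with single peaks (624 bp, 0.00462), as did enteric genes in replicate 1's (886 bp, 0.0160) and Hox groups 10 to 13 in replicate 2's (499 bp, 0.00659), by the permutation test. Among genes of like fold, endothelium (0.00391), blood (0.00884) and Hox groups 10 to 13 (0.00874) passed as wider and proteasome genes (0.0248) as narrower.

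**Figure D3:**
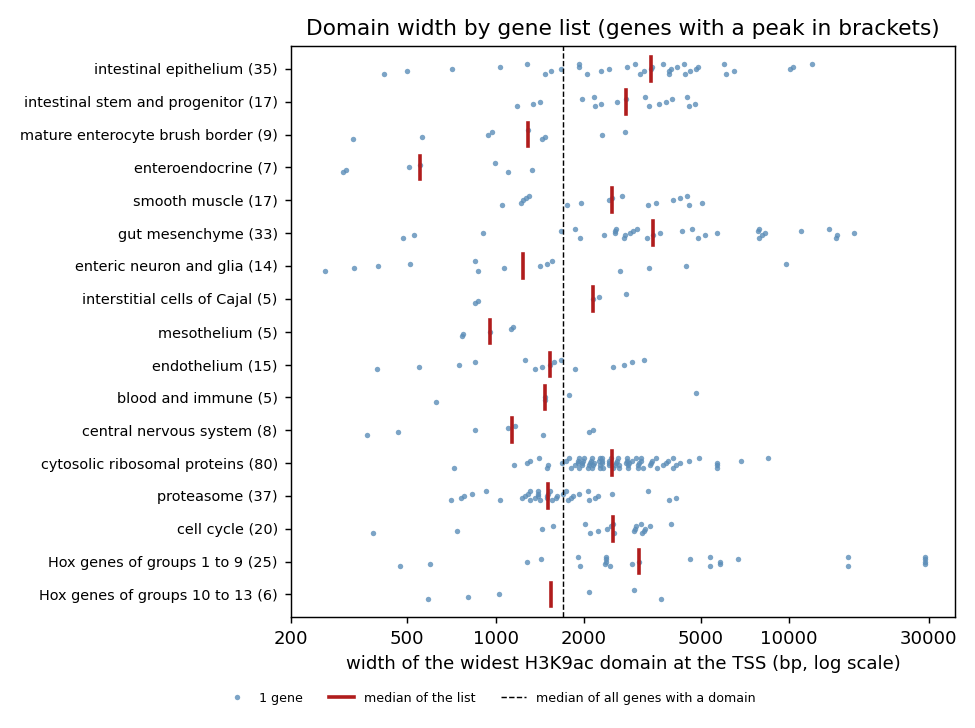
Width of the widest H3K9ac domain at the TSS of each marked gene (points, in bp on a log axis) in the 17 lists with 5 or more such genes, with the median of each list as a red bar and the median of all marked genes, 1700 bp, as a dashed line. Medians are 3435 bp for gut mesenchyme, 3388 bp for intestinal epithelium and 553 bp for enteroendocrine genes.

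**Figure D4:**
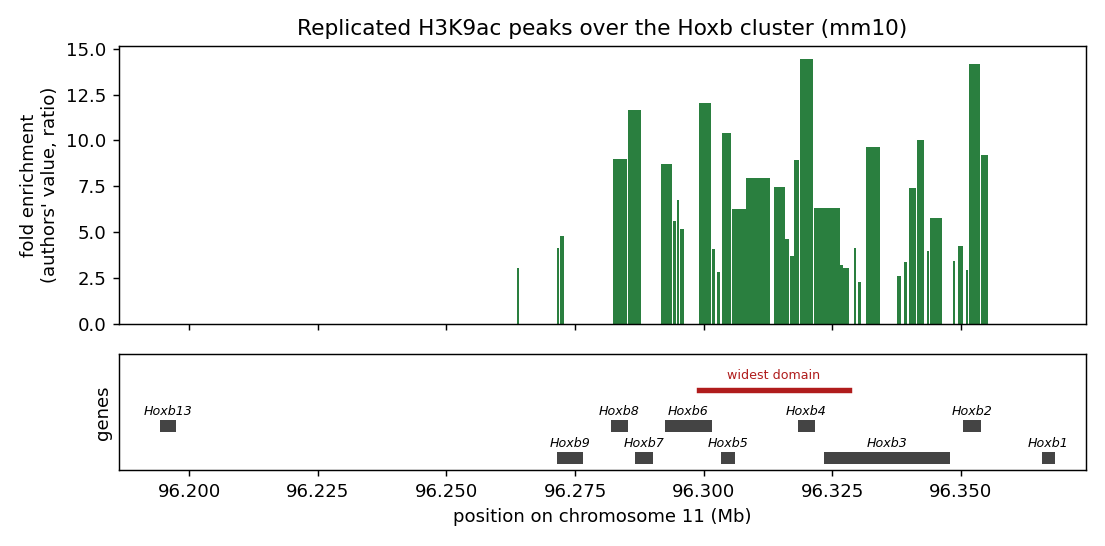
Replicated H3K9ac peaks over the Hoxb cluster on chromosome 11 (mm10, position in Mb on the horizontal axis), drawn at their width and at the authors' fold enrichment (vertical axis, a ratio), above the annotated genes. The red line marks the domain of 29226 bp from the end of Hoxb6 to the start of Hoxb3, and no peak lies at Hoxb1 or Hoxb13.

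H3K9ac sites away from promoters gathered around epithelial and Hox genes. Intestinal epithelium genes had a mean of 2.78 replicated peaks between 2.5 and 100 kb from their 5' end and more than 2.5 kb from any TSS, against 0.962 for other genes (adjusted p = 0.000773 in a permutation test of the mean), and of 6.42 and 6.58 in the longer lists of replicate 1 and replicate 2. In the replicated list the median of these genes was 2. Hnf4a had 6, Cdx1 and Gata5 5 each, Cdx2 and Vil1 4 each and Foxa3 3. Grhl2, Shh and Ihh had 1 each, and Gata6 and Fabp1 had 0. Hox groups 1 to 9 had a mean of 3.00 against 0.963 (adjusted p = 0.000773), although neighbouring Hox genes count the same peaks, and in replicate 1's own list this was not past the threshold (adjusted p = 0.0793, permutation test). Olfactory and vomeronasal receptor genes had fewer, 0.111 against 1.02 (adjusted p = 0.00058, permutation test), and 0.229 and 0.260 in the own lists of replicate 1 and replicate 2. Single peaks were counted, also where they had been joined into a wide domain at a TSS. Distal counts and domain widths may therefore share peaks and are not separate results. Of the 5414 replicated peaks more than 2.5 kb from a TSS, 3914 overlapped a peak in each replicate's own list. The distal counts may therefore include peaks not found in both.

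Gut mesenchyme genes had a mean of 1.97 distal peaks (adjusted p = 0.0725 in the permutation test), and of 4.27 (0.228) and 5.48 (0.0515) in the own lists of replicate 1 and replicate 2. In the replicated list their median was 1, with 9 at Foxf1, 8 at Ptch1, 2 each at Hlx and Meis2 and 1 each at Meis1 and Gli1. The list passed within 50 kb (1.39 peaks, adjusted p = 0.00319, permutation test) and against genes of like gene density (0.00406). Cytosolic ribosomal protein genes, at 1.35 (adjusted p = 0.283), passed as higher only in the replicates' own lists, at 4.53 (0.00213) in replicate 1 and 5.27 (0.00261) in replicate 2, by the permutation test. None of the 25 lists left, these genes included, passed in the replicated list, among them stem and progenitor genes at 1.56, smooth muscle at 1.61, endothelium at 1.32, photoreceptors at 2.30 and cell cycle genes at 1.9.

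The distal peaks with the highest fold lay near Zfp869, Pogz, Spag6, Ppara and Pum2 as the nearest protein-coding genes. The first, 704 bp wide, spanned chromosome 8, positions 69716248 to 69716951, 5.88 kb from the 5' end of Zfp869, with a fold of 22.7 in the replicated list, 19.2 in replicate 1 and 16.7 in replicate 2. The second lay on chromosome 3, positions 94820952 to 94821955, 16.1 kb from Pogz, at a fold of 20.1, and the others at folds of 19.2, 18.97 and 18.0. The peak nearest to Ppara, on chromosome 15, positions 85669628 to 85672449, lay within the non-coding gene Lncppara, and the others overlapped no gene of the GENCODE annotation. In the RefSeq annotation, a transcript 5' end lay within 1 kb of the peaks nearest to Zfp869 and Pogz. The peaks nearest to Zfp869, Spag6, Ppara and Pum2 had CpG-rich sequence.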

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

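Replicated peaks outside chromosomes 1 to 19 and X were used in no comparison, and 7 of them held signal. Of these, 2 lay on the Y chromosome and 5 on unplaced sequences, with a highest fold of 11.99. The Y peaks lay at the starts of Kdm5d, which encodes a histone demethylase, and Uty, its neighbour in function on the Y. The first, at positions 897894 to 898141, had a fold of 3.44, and the second, at positions 1245099 to 1245687, a fold of 3.99, with their middles 229 and 367 bp from the gene's 5' end. The replicates' own lists held 2 and 3 peaks on the Y, and the labels give pooled embryos of both sexes. No explanation was tested for these peaks.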

How the results depend on the processing

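The matching on fold and the nearest-gene assignment were chosen only after the data were seen. The CpG difference, the epithelium and mesenchyme calls for TSS peaks and domain width, and the epithelium call for distal peaks kept their direction and side of the threshold under every alternative run for them. No paired analysis was possible because there is 1 group. Depth is unknown, so the effect of list length was seen only through peak thresholds and equal lists.

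Overlap of replicate 1 with 2, and of 2 with 1, was 57.7% and 50.4% at 1 bp, 40.5% and 36.3% at 50% of both peaks, 65.3% and 61.2% at a −log10 q of 2 or more, 87.4% and 81.8% at a fold of 4 or more, and 52.8% and 51.1% with equal lists. The rank correlation was 0.910 on −log10 p, 0.868 at a −log10 q of 2 or more and 0.530 over 2.5 kb from a TSS. Pooled peaks in the replicated list made up 58.8% at a −log10 q of 2 or more. Peaks in 1 replicate alone lay at a TSS in 22.4% and 21.9% of cases at 1 bp and in 29.7% and 30.3% at a −log10 q of 2 or more.

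Replicated peaks at a TSS made up 67.6% with a window of 500 bp, 80.7% with 2.5 kb, 88.8% at a fold of 4 or more and 49.3 to 53.6% in the replicates' own lists. Genes with a TSS peak made up 64.4% with 2.5 kb, 58.956% at a fold of 4 or more, 60.5% from the 5' end alone and 64.6 to 65.6% in the replicates' own lists.

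For TSS peaks of gene lists, 19 alternative values lost a call, 5 gained one and 6 changed direction, and 16 to 25 lists were called, against 23. Endothelium, not called, fell below other genes at 500 bp (59.1%), at a fold of 4 or more (45.5%) and from the 5' end alone (50%), and mesothelium, at 62.5% and also not called, rose above them from the 5' end alone, with the nearest gene only and within CpG classes. At a fold of 4 or more smooth muscle lost its call (83.3%), and enteric neurons and glia (30.8%) and Hox groups 10 to 13 (25%) gained one as lower. Within CpG classes, where shares stay as they are, calls were lost for stem and progenitor (94.4%), brush border (36%), goblet and Paneth (25%) and blood (20.8%) genes and gained for Cajal cells (100%), since the expected share follows the class. In the replicates' own lists the range was 37.5 to 43.8% for goblet and Paneth, 40 to 44.0% for brush border and 88.9 to 94.4% for smooth muscle genes.

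For domain width, single peaks put smooth muscle (1045 bp) and endothelium (1368 bp) on the other side of other genes, and joining over 3 kb did so for Hox groups 10 to 13 (2231 bp). In the replicates' own lists 10 of 19 (4 narrower) and 14 of 21 (7 narrower) lists were called, against 8 of 17 (1 narrower), with nervous system genes narrower in each (311 to 372 bp), enteric genes in replicate 1's and Hox groups 10 to 13 in replicate 2's. Medians there were 1174 to 1677 bp for endothelium, 499 to 1086 bp for Hox groups 10 to 13, 2246 to 2396 bp for smooth muscle and 886 to 1041 bp for enteric genes. Relative to genes of like fold, on the log2 scale, the median was -0.29 for enteroendocrine genes, whose call was lost, and 0.43 for enteric neurons and glia, 0.71 for endothelium, 1.15 for blood, 0.54 for the nervous system and 1.01 for Hox groups 10 to 13, which turned from narrower to wider, with a call gained for endothelium, blood and Hox groups 10 to 13. Proteasome genes gained one as narrower (-0.32). For distal peaks, mesenchyme gained a call within 50 kb (1.39) and against genes of like density (1.97), epithelium ranged from 6.42 to 6.58 and mesenchyme from 4.27 to 5.48 in the replicates' own lists, ribosomal protein genes gained one in each of these (4.53 to 5.27), and Hox groups 1 to 9 ranged from 4.93 to 7.96 there, the lower value without a call. The cause was not tested for any of these, apart from the CpG classes.

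Of the 24 genes fixed by name, Atoh1, Sox10 and Pdx1 lost their TSS peak at a fold of 4 or more, Sox10 also with a window of 500 bp and from the 5' end alone, Myh11 lost it in replicate 1's own list, Sox2 and Myod1 gained one there, and Muc2 gained one with a window of 2.5 kb.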

Other observations

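The gene families and non-coding genes in the opening paragraphs were chosen after the data were seen, as were the tests of repeated sequence and of wide domains further on. Hedgehog pathway genes were marked throughout, from ligands to targets: all 14, Boc, Cdon, Dhh, Gas1, Gli1, Gli2, Gli3, Hhip, Ihh, Ptch1, Ptch2, Shh, Smo and Sufu, had a TSS peak (adjusted p = 0.0158 over 14 families by Fisher's exact test, and 0.0248 within CpG classes). Of the hedgehog genes, Shh and Ihh are also in the epithelium list, and Gli1, Gli2, Gli3, Hhip and Ptch1 in the mesenchyme list. The family is therefore not separate from those results. Paired box genes, which pattern neural tube, kidney, thyroid and muscle, were nearly unmarked, with Pax6 the only 1 of 9 (adjusted p = 0.0139 by Fisher's exact test, and 3.26e-05 within CpG classes). Iroquois genes were marked in 3 of 6 cases, against 95.8% expected from their CpG-rich promoters (adjusted p = 0.676 by Fisher's exact test, and 0.00921 within CpG classes). All 10 Frizzled receptor genes (0.0478), 16 of 17 Krueppel-like factor genes (0.0325) and 56 of 67 histone genes of the Hist clusters (0.00470) passed by Fisher's exact test. Within CpG classes those families had adjusted p of 1.00, 0.585 and 0.585. Wnt ligands (15 of 19), fibroblast growth factors (13 of 22), Bmp ligands (9 of 11), Sox (14 of 19), Fox (31 of 44) and T-box genes (8 of 16), claudins (11 of 24) and the 7 Meis and Pbx genes, all marked, did not pass in either test. The Meis and Pbx genes had a median domain of 4692 bp.

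Of Hox genes by cluster, all 11 Hoxa genes had a TSS peak, 8 of 10 Hoxb genes, 7 of 9 Hoxd genes and 5 of 9 Hoxc genes, with no test between clusters. Hoxc11, Hoxc12, Hoxc13 and Hoxd12 had no TSS peak in either replicate's list. Of 7397 non-coding genes more than 2.5 kb from a protein-coding TSS, 605 (8.18%) had a replicated TSS peak. Among the highest folds were Snhg6 at 22.8, Dancr at 21.7 and Mir17hg, the host of the miR-17 microRNA cluster, at 19.5 in the replicated list.

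The X chromosome had few peaks: 3.78 replicated peaks per Mb against 11.5 on the autosomes, and a TSS peak at 42.6% of 948 genes against 64.3% of 20780. Fewer CpG-rich promoters (23.8% of X genes against 45.7%) would bring the X to 51.5%, but among CpG-rich genes the share was still lower, 88.1% (95% Wilson interval 83.2 to 91.7) against 96.0% (95.6 to 96.4), with p = 7.59e-07 by Fisher's exact test, so this cannot be the whole cause. Signal was lower across the X: the median fold of CpG-rich genes with a TSS peak was 7.56 against 13.4, a ratio of 0.564 (95% bootstrap interval 0.541 to 0.589), and 0.574 and 0.590 in the replicates' own lists. A lower signal may therefore account for the rest, and fewer X copies in the pooled tissue or a silent X in female cells remain open, since no sample of known sex was analysed here. No biological explanation was tested.

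Strong peaks far from any annotated TSS may be starts that the gene models lack. Of the 100 distal peaks with the highest fold, 78.0% had a RefSeq 5' end within 1 kb or CpG-rich sequence, against 21.1% of the others (p = 5.06e-33 by Fisher's exact test). Only 38 had the RefSeq end (11.5% of others), while 64 were CpG-rich (11.4%), which is no direct sign of a start. Repeated sequence was argued against: 0 of the 100 had over 50% soft-masked bases (95% Wilson interval 0 to 3.70%). Among the other distal peaks 0.565% did, so such peaks were rare at any fold and the count does not set the 100 apart. The median soft-masked share of the 100 was 8.69% against 7.19% in other distal peaks (p = 0.113, permutation test). Recent copies of genes are not soft-masked and remain open, 22 of the 100 had neither feature, and no biological explanation was tested.

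Wide domains at epithelial and mesenchymal genes, with a median of 3405 bp over 68 genes against 1696 bp, were kept in 3 tests, each with p = 2e-05, the smallest the permutations can give. Among CpG-rich promoters the median was 3669 bp against 1869 bp. With domains at 1 protein-coding gene only it was 3421 bp against 1551 bp. Relative to genes of like fold it was higher by 1.34 on the log2 scale. These values argue against CpG content, joined protein-coding neighbours or a stronger signal as the whole cause. Domains that also reached the promoter of a non-coding gene were not removed, so joining with those remains open. Relative to genes of like fold, 10 of 17 lists passed as wider and 1 as narrower. A greater width at like fold was thus not particular to these genes. Gut mesenchyme (1.49) and intestinal epithelium (1.33) had the highest medians among the 10. Others among them were Hox groups 1 to 9 (1.19), blood (1.15), smooth muscle (1.13), Hox groups 10 to 13 (1.01) and endothelium (0.71). No biological explanation was tested.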
